A study of Mus musculus with 10 samples.

How the data were processed

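Bone-marrow-derived macrophages from C57BL/6J mice were left untreated or treated with Kdo2-lipid A at 0.03 nM or 10 nM for 1 h or 2 h, and polyadenylated RNA was sequenced in 10 libraries, 2 for each of 5 groups, per the labels. Per the labels' protocols, RNA was isolated with Qiazol and a Zymo column kit, libraries were made with the NEBNext Ultra Directional kit, and these were sequenced on a NextSeq 500. The submitters' processing notes name bcl2fastq 2.15.0.4, TopHat2 2.0.11, featureCounts 1.4.5-p1 of the Subread package, DESeq2 and the mm9 genome, without stating the role of each. The deposited raw counts are whole numbers of reads over the exons of gene models, with the columns that featureCounts writes, per the file headers. The second deposited table holds the same genes as regularised log2 (rlog) values made by the authors from scaled counts. The versions of Subread and DESeq2 and the options of that transformation are not given in the sources used here. The strand setting of the counting is not given there either, so genes that overlap on opposite strands cannot be separated, and counts of gene family members that share sequence are uncertain. Chromosome, start and end of each gene are those in the count table. A GRCm38 annotation was used only for symbols, synonyms and GC content; exonic length is that in the count table.

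The count table has 23284 genes, and library totals run from 33179599 to 42167096 counts. The pre-ribosomal RNA gene took 0.616% to 1.35% of them and was kept. Raw counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 5 groups (12918 genes), libraries were scaled by TMM, and one quasi-likelihood model with robust estimation and one mean per group was fitted to all 10 libraries, which leaves 5 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The 9 contrasts were each stimulated group against untreated cells, 10 nM against 0.03 nM at each time, 2 h against 1 h at each dose, and the interaction of dose and time. The labels give each library an experiment number. Deviations of the libraries from their group means, checked between groups, correlated at 0.0397 to 0.236 (median 0.177; 7 of 10 pairs of groups above 0.1). The planned model has no block for the experiment, and the block is one of the alternatives.

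Before the data were examined, the 24 gene lists tested were fixed from general knowledge: immediate-early genes, NF-kB feedback genes, inflammatory cytokines, chemokines, interferon-stimulated genes, anti-inflammatory regulators, MAP kinase phosphatases and feedback inhibitors, effector enzymes, TLR4 signalling components, co-stimulation and adhesion genes, macrophage identity genes, phagocyte and G protein-coupled receptors, glycolysis, sterol synthesis, LXR targets, cell cycle, heat shock and stress, reference genes, and markers of neutrophils, dendritic cells, B cells, erythroid cells, mast cells and stromal or endothelial cells. A list of T and NK cell markers had fewer than 3 tested members and was not tested. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over lists. The test was repeated with an estimated correlation. Where a called list is given without that second camera value, it passed there too, at adjusted p of 0.0076 to 0.0495. The fry test, which does not compare a list with other genes, was run beside it. Its p-values are unadjusted and are given only where fry is named. The members of each list were also adjusted over that list alone. The genes named were chosen by a rule fixed at the same point: for each comparison with untreated cells and between doses, the 8 largest rises and 6 largest falls among called genes with a mean of at least 1 log2 CPM and the same sign in both experiments. Comparisons over time and the interaction gave the 5 largest each way, and changes called largest below are so within this filter. Added were up to 4 members of each list by smallest p (all called members where 5 or fewer were called) and a fixed panel of cytokine, chemokine and signalling genes at each step. Where space was short, genes were taken in that order, some genes the rule selects are not used here, and genes named outside the rule are said to be so.

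The share of the 10 nM response reached at 0.03 nM is the ratio of the log2 fold changes over genes called and raised at least 2-fold at 10 nM, summarised by its median, and lists were compared with other raised genes by 10000 permutations over genes, repeated, as a test chosen after the result was seen, without genes of at most 3 counts over the untreated libraries. For genes with 1 to 3 counts over the untreated libraries, the ratio is given with a 95% counting interval, and with 0 counts as a lower bound at a floor of 3 counts. Overlaps of calls were set against independent lists and 40 simulations. In these no gene changed, all libraries were redrawn from the untreated means without a difference between experiments, and only the untreated libraries were shared. The pipeline was tested on simulated data built on 10 nM 1 h against untreated cells. Of 50 genes changed by each of 1.5-fold, 2-fold, 4-fold and 8-fold, 66%, 84%, 92% and 100% were recovered. There 12 of 183 calls were false over 12772 genes. Alternatives were DESeq2 size factors or library totals in place of TMM, no filter on low counts, the DESeq2 1.42.0 Wald test, limma on the deposited regularised log2 values, and a block for the experiment. Others were only the groups compared, each library left out in turn, an estimated correlation for lists, and genes raised at least 4-fold for the share. Removal of a trend with exonic length in each library was added after the data were seen.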

Results

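Polyadenylated RNA was sequenced from bone-marrow-derived macrophages of C57BL/6J mice, phagocytes grown from marrow progenitors in macrophage colony-stimulating factor. Cells were left untreated or received Kdo2-lipid A, the lipopolysaccharide core that activates Toll-like receptor 4 (TLR4), at 0.03 nM or 10 nM for 1 h or 2 h. The labels place the untreated libraries at 0 h, and there was no untreated group at 1 h or 2 h. Changes against untreated cells thus cannot be separated from effects of time or handling, unlike differences between doses at the same time. Each of the 5 groups held 2 libraries, one from each of 2 experiments that the labels describe as independent, 10 libraries in all. The question posed by this design is which transcripts respond to a low and to a high dose of one TLR4 ligand, and how soon.

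The count table covered 23284 genes placed on the mm9 mouse genome, of which 6164 had no count in any library and 12918 were tested. Totals ran from 33179599 counts in the 0.03 nM 2 h library of experiment 1 to 42167096 in the 10 nM 1 h library of experiment 2. The SD of the log2 difference between the 2 libraries of a group was 0.289 at 0.03 nM 2 h and 0.156 to 0.209 in the other groups. Across 8358 genes, that difference (experiment 2 minus experiment 1) correlated with exonic length at Spearman rho = -0.683 at 0.03 nM 2 h and at -0.0288 to 0.371 in the other groups. Genes are not independent replicates. Marker genes of stromal and endothelial cells were higher in experiment 2 in each group, 10 to 12 of 12 genes, with median log2 differences of 0.893 to 1.13. Interferon-stimulated genes were also higher in experiment 2, in 31 of 31 genes in untreated cells (median 0.51) and in 31 of 31 at 0.03 nM 1 h (median 1.03). The other groups gave 24 of 31 at 0.03 nM 2 h (median 0.18), 29 of 31 at 10 nM 1 h (0.25) and 31 of 31 at 10 nM 2 h (0.31). Values below are CPM, the counts scaled to a common total, after scaling by the trimmed mean of M values (TMM), as mean ± SD of 2 libraries, and log2 fold changes ± SE, and positions are gene spans on mm9.

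After 1 h at 0.03 nM, the neutrophil-attracting chemokines Cxcl1 and Cxcl2 rose most, 56.5-fold and 45.7-fold over untreated cells. Cxcl1 (chromosome 5, 91320271 to 91322141) went from 0.216 ± 0.0696 to 12.4 ± 0.579 CPM and Cxcl2 (chromosome 5, 91332925 to 91334964) from 1.4 ± 0.402 to 64.3 ± 19.0 CPM. Socs3, a feedback inhibitor of cytokine receptor signalling, rose 26.3-fold, and Tnf (chromosome 17, 35336336 to 35338941), the founding inflammatory cytokine, rose 17.9-fold from 8.82 ± 1.5 to 158 ± 40.4 CPM. Dusp2, a nuclear MAP kinase phosphatase, rose 13-fold, the transcription factor gene Maff 12.8-fold, the interleukin gene Il1b 12.1-fold (8.08-fold without the 0.03 nM 1 h library of experiment 2), and Smad6, which encodes an inhibitory SMAD of the bone morphogenetic protein (BMP) pathway, 11.1-fold. The largest falls were in membrane transport genes: the organic anion transporter gene Slco4a1 was 3.32-fold lower, the inositol transporter gene Slc5a3 2.89-fold and the betaine transporter gene Slc6a12 2.29-fold. Angptl4, which encodes an inhibitor of lipoprotein lipase, was 1.88-fold lower (not called with a block for the experiment, adjusted p = 0.055), the mitochondrial ribosomal gene Mrps6 1.72-fold and the lysophosphatidic acid receptor gene Lpar5 1.53-fold. The spans of Slc5a3 and Mrps6 overlap on the same strand (chromosome 16, from 92058567 and from 92058581), so their counts may share reads.

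In all, 198 genes changed at 0.03 nM at 1 h, 184 upward and 14 downward (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), 82 of them up and 3 down by at least 2-fold. Among NF-kB feedback genes, which encode inhibitors and subunits of that transcription factor, 11 of 18 rose and 0 fell, 14 when adjusted over the list alone. Camera gave adjusted p = 1.94e-64, or 0.0129 with an estimated correlation. The inhibitor gene Nfkbia rose 4.45-fold (edgeR adjusted p = 2.71e-07). On the log2 scale the ubiquitin-editing gene Tnfaip3 rose by 2.50 ± 0.13 and Nfkbie by 2.06 ± 0.17. Immediate-early genes, the first transcripts induced by many stimuli, rose in 10 of 22 cases, 16 adjusted over the list alone (camera adjusted p = 1.94e-61). Gadd45b rose by 1.48 ± 0.10 and the anti-apoptotic gene Ier3 by 1.33 ± 0.10, and the zinc finger factor genes Egr1 and Nr4a1 both rose by 2.10, with SE of 0.23 and 0.17. Of the chemokines 6 of 17 rose (11 adjusted over the list alone; camera adjusted p = 8.15e-43), and of the inflammatory cytokines 6 of 21 (8 alone; adjusted p = 2.78e-28). Of the co-stimulation and adhesion genes 6 of 15 rose (11 alone; adjusted p = 4.22e-28), with 0 falls in each. The T-cell ligand genes Tnfsf9 and Icosl rose by 3.16 ± 0.14 and 1.28 ± 0.11 and the adhesion gene Icam1 by 1.17 ± 0.11.

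Feedback regulators also rose within 1 h at 0.03 nM. Of 17 anti-inflammatory regulators, 6 rose (7 adjusted over the list alone; camera adjusted p = 1.29e-25), among them the mRNA-destabilising factors Zfp36 and Zc3h12a, by 2.01 ± 0.13 and 1.28 ± 0.09. Of 17 MAP kinase phosphatases and related inhibitors, 7 rose (8 alone; adjusted p = 4.82e-24). Receptors of the phagocyte list rose in 4 of 29 cases (5 alone; camera adjusted p = 7.83e-11, or 0.139 with an estimated correlation). The fatty acid receptor gene Gpr84 stood at 3.22 ± 0.23. Effector enzymes rose in 3 of 22 cases (4 alone; camera adjusted p = 3.57e-08, or 0.249 with an estimated correlation). TLR4 pathway components rose in 3 of 28 cases, among them Tlr2 by 1.20 ± 0.09, with a list median of -0.01 against a mean of 0.10 (5 alone; camera adjusted p = 0.0322, or 0.249 with an estimated correlation). Camera placed the 31 interferon-stimulated genes higher (adjusted p = 0.00253, or 0.691 with an estimated correlation), while 0 of them passed on their own in edgeR (2 at unadjusted p under 0.05; 1 passed in DESeq2 and 0 in limma). This is the list that differed between experiments in untreated cells. Without the 0.03 nM 1 h library of experiment 2 its direction turned downward (camera adjusted p = 0.00448). It was not called without the untreated library of experiment 1 (adjusted p = 0.388), and the TLR4 component list was not called without either untreated library or the 0.03 nM 1 h library of experiment 2 (adjusted p = 0.0897, 0.0724 and 0.163).

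Not called at 0.03 nM at 1 h were glycolysis (0 of 22 genes, 1 adjusted over the list alone), sterol synthesis (0 of 18), liver X receptor (LXR) targets (0 of 12, 1 alone), cell cycle (0 of 24), and reference genes (0 of 13). Nor was the heat shock and stress list, in which 1 of 19 genes rose, the cell cycle inhibitor gene Cdkn1a. Of 24 macrophage identity genes 2 rose, the transcription factor gene Cebpb and the scavenger receptor gene Msr1. Of the other cell type lists, 1 of 13 neutrophil genes was raised, and 0 of 11 dendritic, 0 of 6 B cell, 0 of 5 erythroid, 0 of 4 mast cell and 0 of 12 stromal genes passed. In the lists where edgeR called 0, the genes at unadjusted p under 0.05 numbered 5 in glycolysis, 1 in sterol synthesis, 2 in LXR targets, 1 in cell cycle and 2 in reference genes. In the cell type lists they numbered 3 for dendritic, 0 for B, 1 for erythroid, 0 for mast and 1 for stromal cells. DESeq2 called 1 gene in glycolysis, 1 in LXR targets and 0 in the others, and limma 0 in each. Genes given at each step that did not pass here were Il6 and these, with values of 0.66 ± 0.27 for Il10, 1.72 ± 0.34 for Cxcl10, 0.73 ± 0.54 for Ccl5, 1.46 ± 0.59 for Ifnb1 and 2.14 ± 1.23 for Nos2. Cxcl10 passed in DESeq2 (adjusted p = 0.000127) and with a block for the experiment (adjusted p = 0.0246). With that block Nr1h3 of the LXR list (0.62) and Irg1 of the effector list (3.925) passed as well (edgeR adjusted p = 0.00312 and 0.00615). Counts depended on single libraries: 78 genes changed without the untreated library of experiment 1, 114 without that of experiment 2 and 113 without the 0.03 nM 1 h library of experiment 2. Of 41 named calls, 24 held in each fit that left out 1 library. Those lost, with their highest adjusted p, included Il1b (0.0532 without the 0.03 nM 2 h library of experiment 2) and Egr1 (0.0646 without that of experiment 1). Also lost were Slc5a3, Lpar5 and Msr1 (0.0527, 0.0669 and 0.611 without the untreated library of experiment 1) and Angptl4 and Mrps6 (0.575 and 0.07 without the 0.03 nM 1 h library of experiment 2). Others were Cdkn1a and Cebpb (0.159 and 0.0887 without the 0.03 nM 2 h library of experiment 2). With only the groups compared 19 of the 41 calls were lost. Among them were Cxcl2, Tnf, Socs3 and Il1b (adjusted p = 0.0784, 0.101, 0.261 and 0.326), Nfkbie, Icam1 and Zfp36 (0.164, 0.0822 and 0.0662), and Dusp1, Fos and Ptgs2 (0.334, 0.348 and 0.102). Also lost there were Ccl3, Il12b, Sod2, Irak2 and Adora2a (0.144, 0.218, 0.392, 0.0693 and 0.184) and Angptl4, Cebpb, Msr1 and Cdkn1a (0.0695, 0.25, 0.0571 and 0.433).

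**Figure D1:**
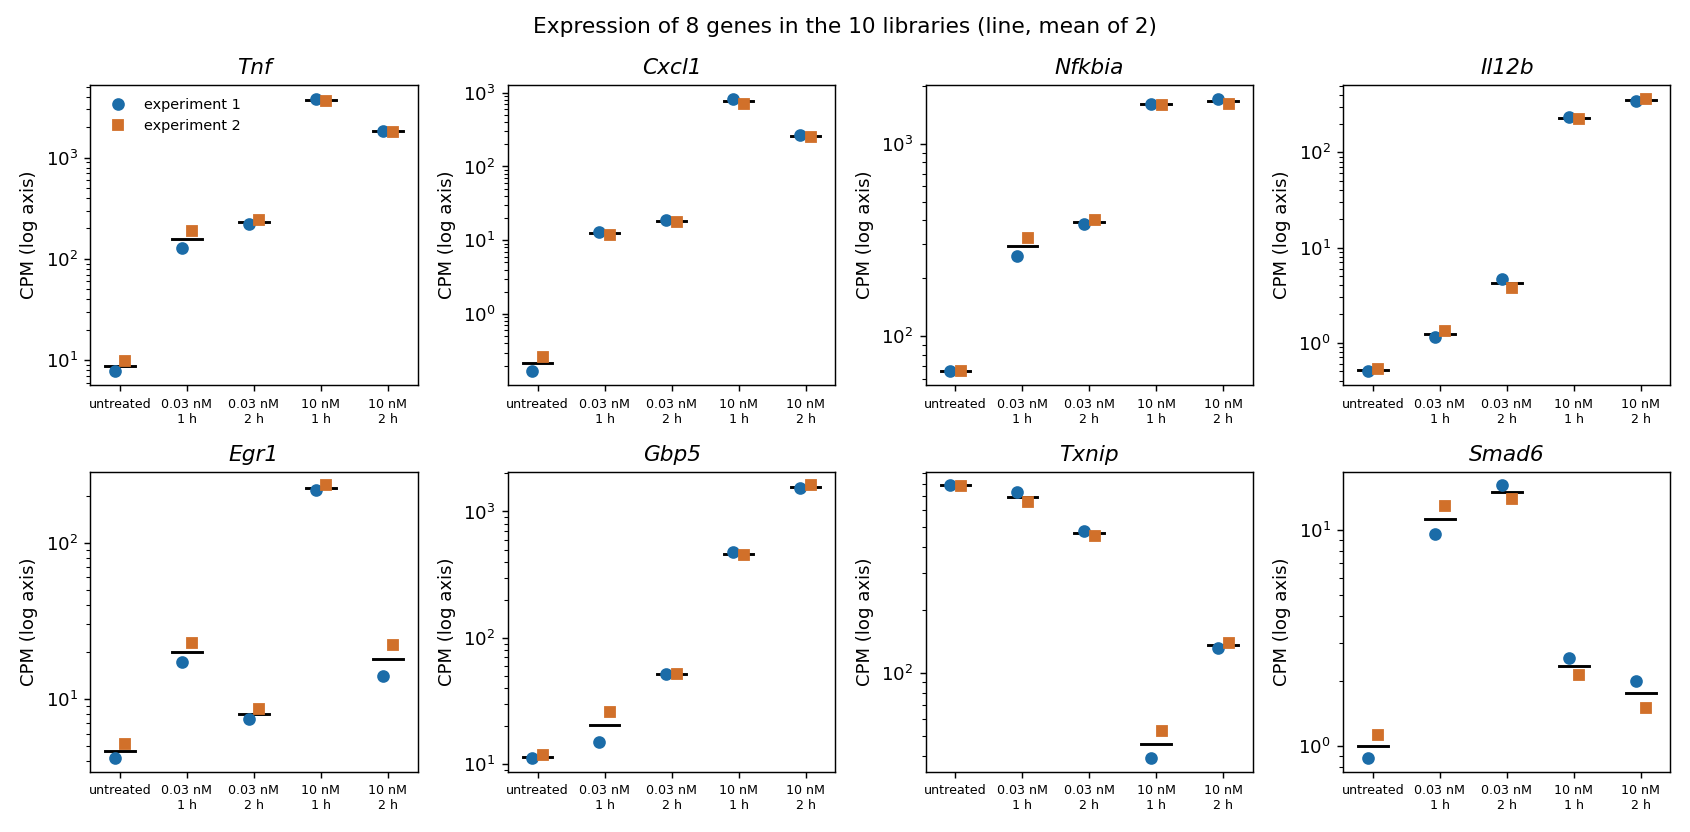
CPM on log axes in each library for Tnf, Cxcl1, Nfkbia, Il12b, Egr1, Gbp5, Txnip and Smad6 by group, with experiment 1 as circles, experiment 2 as squares and a line at the mean of the 2 libraries. Tnf rises at each dose and time, Egr1 is highest at 10 nM 1 h, and Smad6 is highest at 0.03 nM, at 11.2 and 14.9 CPM after 1 h and 2 h.

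At 2 h at 0.03 nM, Irg1, which encodes the enzyme that makes itaconate, was 140-fold above untreated cells (329 ± 33.6 against 2.36 ± 1.51 CPM; 255-fold without the untreated library of experiment 2), Cxcl1 83.6-fold and Cxcl2 67.4-fold, and Gpr84 and Socs3 41.8-fold and 41.6-fold. Olr1, a receptor for oxidised lipoprotein, Il6, the acute-phase cytokine, and Adamts4, an aggrecan-cleaving protease, had 2, 1 and 2 counts over the untreated libraries. They were higher by ratios of 115 (95% counting interval 31.5 to 956), 70.3 (12.2 to 2820) and 50.6 (13.6 to 424). These intervals cover counting error only. Fitted folds without the untreated library of experiment 1 or 2 were 53.4 or 822 for Olr1, 30.8 or 253 for Il6 and 23.5 or 362 for Adamts4. Slc5a3 and Slco4a1 were again among the largest falls, 3.69-fold and 3.47-fold lower, followed by the GSK3-binding gene Frat2 (3.12-fold), the orphan receptor gene Gpr146 (2.87-fold), Lpar5 (2.69-fold) and Angptl4 (2.61-fold).

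At this time 1268 genes changed, 833 upward and 435 downward, with 292 up and 33 down by at least 2-fold (edgeR, Benjamini-Hochberg). NF-kB feedback genes rose in 15 of 18 cases (17 adjusted over the list alone; camera adjusted p = 1.36e-69). Nfkbia stood at 2.57 ± 0.10, Tnfaip3 at 2.79 ± 0.13 and Tnip1, a partner of the Tnfaip3 product, at 1.78 ± 0.09. Chemokines rose in 13 of 17 cases (15 up and 1 down alone; camera adjusted p = 1.08e-45). Ccl3 stood at 2.75 ± 0.17 and the interferon-responsive Cxcl10 at 3.41 ± 0.36. Co-stimulation and adhesion genes rose in 13 of 15 cases (13 alone; adjusted p = 4.63e-45). Icosl stood at 2.84 ± 0.11, Icam1 at 2.40 ± 0.11 and the dendritic maturation marker Cd83 at 2.12 ± 0.11. Inflammatory cytokines rose in 10 of 21 cases (13 alone; camera adjusted p = 1.33e-20, or 0.0521 with an estimated correlation). Tnf stood at 4.72 ± 0.19 and Il12b, a subunit of interleukin 12, at 3.03 ± 0.16. Immediate-early genes rose in 11 of 22 cases (16 alone; camera adjusted p = 1.41e-19, or 0.0554 with an estimated correlation). MAP kinase phosphatases rose in 10 of 17 cases (11 alone; camera adjusted p = 2.48e-14, or 0.0521 with an estimated correlation).

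Anti-inflammatory regulators rose in 8 of 17 cases at 0.03 nM at 2 h (10 adjusted over the list alone; camera adjusted p = 9.98e-16, or 0.0863 with an estimated correlation). Cish, a feedback inhibitor of STAT signalling, stood at 1.6 ± 0.15. Effector enzymes rose in 10 of 22 cases (12 alone; camera adjusted p = 1.7e-13, or 0.136 with an estimated correlation). The superoxide dismutase gene Sod2 stood at 2.08 ± 0.12 and Ch25h, which makes 25-hydroxycholesterol, at 3.47 ± 0.23. Of 29 phagocyte receptors 11 rose and 3 fell (11 and 4 alone; camera adjusted p = 4.2e-09, or 0.148 with an estimated correlation). The adenosine receptor gene Adora2a stood at 3.34 ± 0.16 and the chemokine receptor gene Cxcr4 at -0.96 ± 0.13. TLR4 pathway components rose in 8 and fell in 1 of 28 cases (8 and 1 alone; camera adjusted p = 5.03e-06, or 0.0521 with an estimated correlation). Tlr2 stood at 2.43 ± 0.10 and the kinase gene Irak2 at 1.67 ± 0.10. The 31 interferon-stimulated genes were placed higher by camera (adjusted p = 0.00286, or 0.819 with an estimated correlation), and 3 rose, the guanylate-binding genes Gbp5, Gbp2 and Gbp3, by 2.17 ± 0.20, 0.70 ± 0.15 and 0.74 ± 0.17. That call was lost without the untreated library of experiment 1 or the 0.03 nM 2 h library of experiment 2 (camera adjusted p = 0.135 and 0.163). Those on Gbp2 and Gbp3 were lost without the latter (edgeR adjusted p = 0.223 and 0.229). Reads may be shared among the Gbp genes.

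Macrophage identity genes went both ways at 0.03 nM at 2 h, 4 up and 4 down of 24 (4 and 5 adjusted over the list alone). The scavenger receptor gene Msr1 rose by 1.00 ± 0.08 and Sfpi1, which encodes PU.1, by 0.56 ± 0.10, while the lineage factor genes Irf8 and Cebpa fell by 0.47 ± 0.08 and 0.39 ± 0.09. Glycolysis rose in 4 of 22 cases, with the glucose transporter gene Slc2a1 at 0.62 ± 0.07, and the sterol synthesis list in 4 of 18 (5 alone). Insig1 stood at 0.35, and its call was lost when libraries were scaled by their totals (0.0617). LXR targets gave 1 up (the LXR gene Nr1h3 itself, 1.48 ± 0.15) and 1 down (Abcg1, -0.40 ± 0.08) of 12, and heat shock and stress genes 5 up and 2 down of 19. Cell cycle genes gave 0 up and 1 down of 24. Reference genes gave 1 up and 1 down of 13 (Actb and Tfrc, with 0 up and 1 down under scaling by library totals). No list among these passed camera, and of the other cell type lists only 1 of 13 neutrophil genes rose. Il10, Ccl5, Fos, Egr1 and Nos2 did not pass (0.42, 0.99, 0.92, 0.78 and 2.20), but Fos and Egr1 did with a block for the experiment (adjusted p = 9.71e-05 and 0.00458), in DESeq2 (adjusted p = 0.0247 and 0.00162) and with only the groups compared (adjusted p = 0.0234 and 0.049). Without the 0.03 nM 2 h library of experiment 1 the count was 3128, and without the untreated library of experiment 1 or 2 it was 668 or 650. Of 57 named calls, 46 held in each fit that left out 1 library. Those lost include Sfpi1 (0.0501 without the untreated library of experiment 1), and Abcg1, Insig1, Actb and Tfrc (0.0842, 0.206, 0.28 and 0.206 without that of experiment 2). With only the groups compared 5 of the 57 were lost, these 4 (adjusted p = 0.0517, 0.143, 0.216 and 0.2) and Ifnb1 (0.0845). The share of rises among changed genes was 65.7%, and 48.4% under scaling by library totals.

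At 10 nM, chemokine and cytokine transcripts rose within 1 h. Cxcl1 was 3490-fold above untreated cells (765 ± 94.7 CPM), Cxcl2 2460-fold, the interleukin gene Il1a 2050-fold, Irg1 883-fold and Ptgs2, the inducible cyclooxygenase gene, 831-fold. Against 1, 2 and 2 untreated counts, Il6, Olr1 and Adamts4 were higher by ratios of 5990 (95% counting interval 1080 to 237000), 2830 (784 to 23400) and 1060 (293 to 8750). The growth factor gene Csf2, with 0 counts in untreated cells, was at least 694-fold higher (floor of 3 counts over the group). Folds rested on few untreated counts: without the untreated library of experiment 1 or 2 Il1a was 1280-fold or 5080-fold higher, Il6 2630-fold or 21500-fold, Olr1 1310-fold or 20300-fold and Adamts4 490-fold or 7540-fold. Without that of experiment 2 Irg1 was 1610-fold higher. The largest falls were in genes of zinc finger proteins, Zkscan14 (19.8-fold lower), Zfp955b (17.1-fold), Zfp60 (14.9-fold) and Zfp760 (13.2-fold), in Txnip (17.2-fold), which encodes an inhibitor of thioredoxin and of glucose uptake, and in the WD repeat gene Wdr5b (12.9-fold). Txnip (chromosome 3, 96361880 to 96365780) went from 788 ± 2.01 to 45.7 ± 9.50 CPM. Zinc finger genes belong to families whose members may share reads.

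In total 4761 genes changed at 10 nM at 1 h, 2393 upward and 2368 downward, 919 up and 710 down by at least 2-fold (edgeR, Benjamini-Hochberg). Immediate-early genes rose in 22 of 22 cases (22 adjusted over the list alone; camera adjusted p = 3.39e-46). Egr1 stood at 5.59 ± 0.25, Egr2 at 5.43 ± 0.15, Maff at 8.51 ± 0.20 and Fos at 1.11 ± 0.26. All 17 chemokines rose (17 alone; adjusted p = 2.9e-44). The T-cell attractants Ccl22 and Ccl5 stood at 5.71 ± 0.16 and 3.56 ± 0.57, Ccl3 at 6.26 ± 0.19 and Cxcl10 at 6.51 ± 0.41. Of 21 inflammatory cytokines 20 rose (20 alone; adjusted p = 9.38e-46). Tnf stood at 8.73 ± 0.22, Il1b at 9.23 ± 0.44, Il12b at 8.78 ± 0.14 and Tnfsf9 at 9.58 ± 0.17. The interferon gene Ifnb1, which is in no list, rose by 9.64 ± 0.28. NF-kB feedback genes rose in 17 of 18 cases (18 alone; adjusted p = 4.32e-48). Nfkbia stood at 4.60 ± 0.11 and Tnfaip3 at 6.79 ± 0.16. Co-stimulation and adhesion genes rose in 14 of 15 cases (15 alone; adjusted p = 1.08e-35). The adhesion genes Vcam1 and Icam1 stood at 5.44 ± 0.17 and 4.71 ± 0.12. MAP kinase phosphatases and inhibitors rose in 13 of 17 cases and fell in 1 (13 and 1 alone; adjusted p = 2.2e-20). The receptor inhibitor gene Errfi1 stood at 6.92 ± 0.14 and Dusp1 at 6.49 ± 0.33.

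Anti-inflammatory regulators rose in 13 of 17 cases at 10 nM at 1 h (14 adjusted over the list alone; camera adjusted p = 4.28e-20, or 0.0562 with an estimated correlation). Il10 stood at 5.07 ± 0.27 and Cish at 5.08 ± 0.13. Effector enzymes rose in 18 of 22 cases (18 alone; camera adjusted p = 1.78e-18, or 0.0774 with an estimated correlation). Ch25h stood at 6.83 ± 0.20 and the nitric oxide synthase gene Nos2 at 4.87 ± 0.89. Components of the TLR4 pathway rose in 18 and fell in 3 of 28 cases (18 and 3 alone; adjusted p = 2.84e-07). The co-receptor gene Cd14 stood at 2.59 ± 0.09 and the kinase gene Mapkapk2 at 2.54 ± 0.08. Under scaling by library totals 12 rose and 9 fell. Phagocyte receptors gave 14 up and 1 down of 29 (14 and 1 alone; camera adjusted p = 4.95e-07, or 0.218 with an estimated correlation), against 11 up and 7 down under library totals. Of 31 interferon-stimulated genes 10 rose (10 alone; camera adjusted p = 0.00757, or 0.847 with an estimated correlation). Gbp5 stood at 5.33 ± 0.23 and the RNA sensor gene Ifih1 at 2.52 ± 0.22, while the antiviral GTPase gene Mx1 stood at 0.57 ± 0.45. This list's call was lost without either 0.03 nM 2 h library (0.086 and 0.0848).

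Metabolic and stress lists at 10 nM at 1 h depended on the scaling. Glycolysis gave 8 up and 1 down of 22 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0285, or 0.515 with an estimated correlation). Slc2a1 stood at 2.34 ± 0.08. Under library totals the list gave 5 up and 11 down (camera adjusted p = 0.19), and its call was lost without either 0.03 nM 1 h library or the untreated library of experiment 2 (0.0567, 0.0569 and 0.0526). Sterol synthesis gave 8 up and 0 down of 18 (8 and 1 alone; camera adjusted p = 0.00855, or 0.447 with an estimated correlation). Insig1 stood at 1.61 ± 0.09. Under library totals the list gave 6 up and 7 down. Heat shock and stress genes gave 11 up and 2 down of 19 (11 and 2 alone; camera adjusted p = 0.000125, or 0.0774 with an estimated correlation). The chaperone gene Hspa1b, which has a near-identical neighbour, stood at 4.71 ± 0.23 and Cdkn1a at 4.28 ± 0.17, and under library totals the list gave 9 up and 7 down. Of 24 macrophage identity genes 6 rose and 3 fell, among them Cebpa at -1.46 ± 0.09 (3 up and 11 down under library totals). Of 12 LXR targets 3 rose and 2 fell (2 and 7 under library totals), and of 24 cell cycle genes 3 rose and 1 fell (1 and 19). The proliferation marker gene Mki67 stood at 2.33 ± 0.12. Of 13 reference genes 4 rose and 3 fell (0 and 9). Camera called none of these 4 lists, nor the lists of neutrophil (2 of 13 up), dendritic (1 of 11), B cell (1 of 6), mast cell (1 of 4), erythroid (0 of 5) and stromal genes (0 of 12). In the erythroid and stromal lists 0 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 and limma called 0. Against untreated cells the median of all genes was -0.38 at 1 h and -0.59 at 2 h under library totals (-0.02 and -0.03 under TMM), and the share of rises went from 50.3% to 15.9% and from 48.8% to 19.4%. Changes are given relative to TMM. The 1789 genes raised at least 2-fold at 10 nM took 10.6% and 11.2% of counts in untreated cells, 27.6% and 27.9% at 10 nM 1 h and 33.6% and 34.7% at 2 h. Of the named calls, Fos alone among the genes given here was lost when a library was left out (0.0605 without the untreated library of experiment 1).

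By 2 h at 10 nM, transcripts of Il6, Il12b and the protease gene Adamts4 stood higher still, while those of Cxcl1, Cxcl2 and Tnf were lower than at 1 h. Irg1 was 1830-fold above untreated cells, Il1a 1620-fold, and Cxcl1 1180-fold. Il12b (chromosome 11, 44213565 to 44227519) was 690-fold higher (0.515 ± 0.0213 to 358 ± 12.9 CPM), and Rnd1 679-fold. Il6, Olr1 and Adamts4 stood at ratios of 11400 (95% counting interval 2040 to 450000), 3640 (1010 to 30100) and 2730 (755 to 22600). Without the untreated library of experiment 1 or 2 Il1a was 1010-fold or 4010-fold higher, Il6 4970-fold or 40600-fold, Olr1 1690-fold or 26100-fold and Adamts4 1270-fold or 19500-fold. Irg1 was 3330-fold higher without that of experiment 2. The largest falls were in Bmf, a pro-apoptotic BCL2 family gene (59.3-fold lower), the DnaJ family gene Dnajc28 (40-fold) and a set of G protein-coupled receptors: Cnr2, a cannabinoid receptor (38.8-fold), Lpar6 (36.4-fold) and Cxcr4 (25.4-fold). The uncharacterised gene AI467606 was 22.2-fold lower. Bmf (chromosome 2, 118354493 to 118375414) went from 56.8 ± 0.62 to 0.958 ± 0.241 CPM and Cxcr4 from 160 ± 16.5 to 6.30 ± 1.25 CPM.

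At 10 nM at 2 h, 7580 genes changed, 3698 upward and 3882 downward, with 1688 up and 1684 down by at least 2-fold (edgeR, Benjamini-Hochberg). Interferon-stimulated genes rose in 29 of 31 cases (30 adjusted over the list alone; camera adjusted p = 1.07e-07, or 0.502 with an estimated correlation). The estimated correlation of this list was 0.924. It is taken from deviations within groups, which include the difference between experiments because the model has no block. In this group 31 of 31 of these genes were higher in experiment 2. The second camera value thus cannot tell a weak shift from that difference, here or in the other comparisons of this list. No such value with the block is given. Gbp5 stood at 7.10 ± 0.24, Mx1 at 5.03 ± 0.52 and Ifih1 at 3.72 ± 0.23. All 22 effector enzymes rose (22 alone; camera adjusted p = 1.72e-15, or 0.148 with an estimated correlation). Nos2 stood at 8.66 ± 0.73 and the collagenase gene Mmp13 at 7.44 ± 0.23. Chemokines rose in 16 of 17 cases (16 alone; adjusted p = 3.03e-29). Cxcl9, a T-cell chemokine, stood at 7.09 ± 0.22 and Ccl5 at 5.57 ± 0.62. Co-stimulation genes rose in 15 of 15 (15 alone; adjusted p = 4.39e-27). Inflammatory cytokines rose in 20 of 21 cases (20 alone; camera adjusted p = 3.03e-29, or 0.0527 with an estimated correlation), and NF-kB feedback genes in 18 of 18 (18 alone; camera adjusted p = 1.13e-29, or 0.0536 with an estimated correlation). The subunit gene Nfkb1 stood at 2.76 ± 0.08. Immediate-early genes gave 18 up and 4 down of 22 (18 and 4 alone; camera adjusted p = 2.15e-08, or 0.197 with an estimated correlation). Gadd45b stood at 4.79 ± 0.11, Egr1 at 1.96 ± 0.23 and Fos at -1.93 ± 0.27. Anti-inflammatory regulators rose in 14 of 17 cases (14 alone; camera adjusted p = 1.75e-15, or 0.122 with an estimated correlation). Cish stood at 7.21 ± 0.13 and Socs1, an inhibitor of interferon signalling, at 6.68 ± 0.32. MAP kinase phosphatases gave 11 up and 3 down of 17 (11 and 3 alone; camera adjusted p = 7.73e-07, or 0.164 with an estimated correlation).

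TLR4 components gave 20 up and 3 down of 28 at 10 nM at 2 h (21 and 3 adjusted over the list alone; camera adjusted p = 2.51e-06, or 0.0536 with an estimated correlation), against 14 up and 10 down under library totals. Phagocyte receptors gave 15 up and 6 down of 29 (16 and 7 alone; camera adjusted p = 0.000166, or 0.367 with an estimated correlation). Adora2a stood at 6.87 ± 0.15, and under library totals the list gave 13 up and 15 down. Glycolysis gave 10 up and 2 down of 22 (10 and 2 alone; camera adjusted p = 0.00222, or 0.345 with an estimated correlation). The regulator gene Pfkfb3 stood at 2.92 ± 0.09 and the hexokinase gene Hk2 at 2.30 ± 0.11, and under library totals the list gave 7 up and 13 down. Heat shock and stress genes gave 10 up and 3 down of 19 (10 and 3 alone; camera adjusted p = 0.00957, or 0.231 with an estimated correlation). The chaperone gene Dnaja1 stood at 1.76 ± 0.07, and under library totals the list gave 9 up and 8 down. Camera called no other list. Macrophage identity genes gave 10 up and 5 down of 24, with Msr1 at 3.05 ± 0.09 and Cebpa at -2.74 ± 0.09 (5 up and 15 down under library totals), and cell cycle genes 2 up and 13 down of 24, with the cyclin gene Ccne2 at -1.83 ± 0.18 (1 up and 21 down). LXR targets gave 2 up and 5 down of 12, with the cholesterol exporter gene Abcg1 at -1.25 ± 0.08 and the small GTPase gene Arl4c at -1.93 ± 0.09 (0 up and 8 down). Their median was 0.08 while their mean was -0.26. Sterol synthesis gave 6 up and 3 down of 18 (6 up and 10 down). Reference genes gave 6 up and 4 down of 13 (2 up and 10 down). Actb stood at 0.96 ± 0.07 and Ywhaz at 1.01 ± 0.07. Fry, which does not compare with other genes, gave unadjusted p = 8.73e-06 for LXR targets and 0.000727 for sterol synthesis. For reference, macrophage identity and cell cycle genes fry gave 0.00289, 0.00366 and 0.00415. Of the other cell types, 4 of 13 neutrophil, 6 of 11 dendritic and 2 of 12 stromal genes rose, and 2 of 6 B cell genes fell. Erythroid and mast cell genes gave 1 up and 1 down of 5 and 1 up of 4. All 70 named calls of this comparison held in each fit that left out 1 library.

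**Figure D2:**
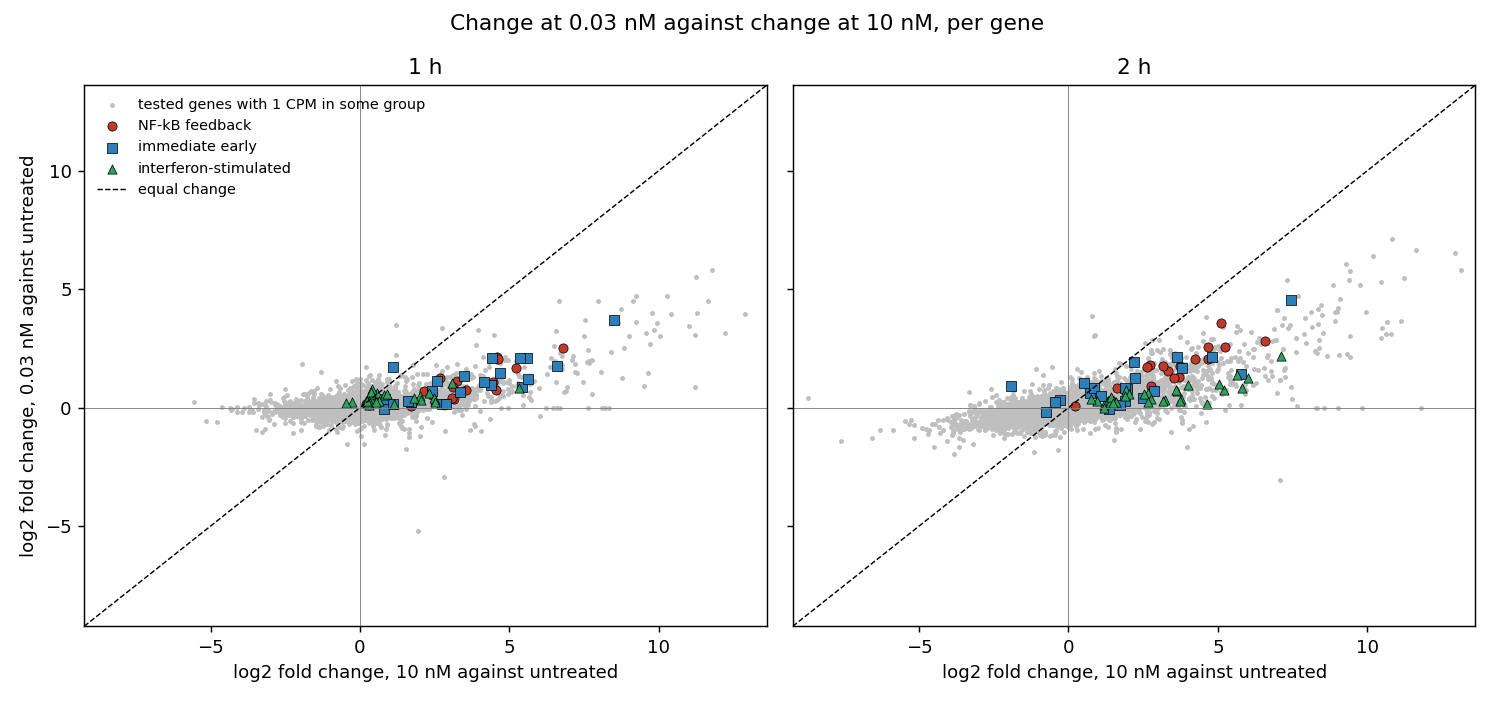
Log2 fold change against untreated cells at 10 nM (horizontal axis) and 0.03 nM (vertical axis), at 1 h and at 2 h. Each point is a tested gene with 1 CPM in some group. NF-kB feedback, immediate-early and interferon-stimulated genes are coloured, and a dashed line marks equal change. Most raised genes lie below the line. Of the 2368 tested genes called lower at 10 nM at 1 h, 5 were also called lower at 0.03 nM. At 2 h 400 of 3882 were, out of 435 called lower at 0.03 nM.

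Each dose was also tested directly against the other. The ranking here is among called genes with a mean of at least 1 log2 CPM and the same sign in both experiments. At 1 h the largest differences upward at 10 nM were in Il6 (531-fold), Ifnb1 (289-fold), Il1a (189-fold), Il12b (184-fold), Olr1 (156-fold) and Ptgs2 (128-fold). At 2 h they were in Il6 (161-fold), Rnd1 (154-fold), Il1a (134-fold), Ptgs2 (114-fold), Mmp13 (96-fold) and Il12b (84.6-fold). Over the 0.03 nM 1 h libraries Il6 and Olr1 had 11 and 36 counts. Without that of experiment 1 or 2 the 1 h folds were 329 or 1400 for Il6 and 94 or 459 for Olr1, and without that of experiment 2 Il1a was 283-fold higher. Lower at 10 nM were Zkscan14 (18.5-fold), Zfp955b (17.4-fold), Txnip (15.2-fold), Zfp60 (14.6-fold) and Zfp870 (13.4-fold) at 1 h, and Bmf (30.6-fold), Cnr2 (27.1-fold), Dnajc28 (24.5-fold), Lpar6 (22.1-fold) and the hydrolase gene Abhd15 (14.2-fold) at 2 h. The doses differed at 4558 genes at 1 h, 2320 higher and 2238 lower at 10 nM, and at 6827 genes at 2 h, 3313 higher and 3514 lower (edgeR, Benjamini-Hochberg). By 2-fold or more, 830 were higher and 702 lower at 1 h, and 1399 higher and 1379 lower at 2 h. Under library totals the share higher fell from 50.9% to 15.5% and from 48.5% to 18.4%, where the median of all genes was -0.37 and -0.52 (-0.01 and -0.03 under TMM).

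Chemokines were higher at 10 nM in 17 of 17 cases at both times (17 and 17 adjusted over the list alone; camera adjusted p = 1.35e-39 and 6.21e-24). Cxcl1 stood at 5.95 ± 0.12 and 3.82 ± 0.11. Inflammatory cytokines were higher in 20 of 21 cases at both times (21 and 20 alone; adjusted p = 4.91e-43 and 3.69e-30). Tnf stood at 4.57 ± 0.18 and 2.96 ± 0.17. Co-stimulation genes were higher in 14 of 15 (15 and 14 alone, camera adjusted p = 7.09e-30 and 4.65e-17), although Icosl, at -0.06 ± 0.10, did not pass at 2 h. With an estimated correlation, the chemokine, cytokine and co-stimulation lists were near the threshold at 2 h (camera adjusted p = 0.0476, 0.0495 and 0.0476). NF-kB feedback genes were higher in 16 and 17 of 18 cases (17 and 17 alone; camera adjusted p = 2.37e-34 and 1.33e-15, the second with adjusted p = 0.157 with an estimated correlation). Immediate-early genes were higher in 21 of 22 cases at 1 h (21 up and 1 down alone; adjusted p = 1.11e-33), Fos alone not passing (-0.61 ± 0.25; adjusted p = 0.000588 with a block for the experiment and 0.0116 under library totals). They gave 14 up and 5 down at 2 h (14 and 5 alone; camera adjusted p = 0.000335, or 0.424 with an estimated correlation). MAP kinase phosphatases gave 13 up and 1 down of 17 at 1 h (adjusted p = 8.71e-16) and 9 up and 5 down at 2 h (camera adjusted p = 0.000335, or 0.285 with an estimated correlation). Anti-inflammatory regulators were higher in 13 and 12 of 17 cases, with 1 lower at 2 h (adjusted p = 0.0552 and 0.157 with an estimated correlation), and effector enzymes in 18 and 21 of 22 (adjusted p = 0.0547 and 0.157 with an estimated correlation).

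Interferon-stimulated genes were higher at 10 nM in 10 of 31 cases at 1 h (10 adjusted over the list alone; camera adjusted p = 0.0446, or 0.987 with an estimated correlation). At 2 h 25 of 31 were higher (27 alone; camera adjusted p = 2.83e-08, or 0.512 with an estimated correlation). The 1 h call was lost without the 0.03 nM 1 h library of experiment 1, either 0.03 nM 2 h library or the 10 nM 1 h library of experiment 2 (0.128, 0.266, 0.248 and 0.107). TLR4 components gave 17 up and 3 down at 1 h (adjusted p = 5.57e-07) and 19 up and 4 down of 28 at 2 h (camera adjusted p = 0.000122, or 0.153 with an estimated correlation). Under library totals 13 were up and 10 down, then 13 and 9. Phagocyte receptors gave 14 up and 2 down at 1 h and 17 up and 6 down of 29 at 2 h (adjusted p = 0.359 and 0.553 with an estimated correlation; 11 up and 11 down, then 10 and 12, under library totals). The 2 h call was lost without the 0.03 nM 2 h library of experiment 2 (0.0701). Heat shock and stress genes gave 11 up and 1 down, then 12 up and 4 down of 19 (adjusted p = 0.0547 and 0.184 with an estimated correlation), the 2 h call being lost without the 0.03 nM 2 h library of experiment 1 (0.0798). Glycolysis gave 8 up and 1 down, then 11 up and 1 down of 22 (adjusted p = 0.463 and 0.285 with an estimated correlation; 5 up and 9 down, then 7 and 12, under library totals, where the 1 h list gave camera adjusted p = 0.143). Sterol synthesis gave 7 up and 1 down of 18 at 1 h (camera adjusted p = 0.00749, or 0.43 with an estimated correlation). Actb was higher at 10 nM at 1 h by 0.30 ± 0.07, which turned to -0.05 under library totals.

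Of 184 genes raised by 0.03 nM at 1 h, 172 were also raised by 10 nM. Tested between the doses, 155 of the 184 stood higher at 10 nM and 14 lower. Of 833 raised at 2 h, 766 were also raised by 10 nM, 647 stood higher and 65 lower. Genes changed in the same direction at both doses numbered 172 up and 5 down at 1 h, where independent lists would share 34.1 and 2.57, and 766 up and 400 down at 2 h, where they would share 238 and 131. In 40 simulations of unchanged groups, with all libraries redrawn and the untreated ones shared, at most 0.1 genes were shared on average. No gene changed there, so few were called. That count cannot show how much the untreated libraries add to the overlap where many genes are called. The fold changes covaried at 0.258 and 0.562 against 0.0369 and 0.037 simulated (r = 0.514 and 0.667 against 0.49 and 0.476). The share of all genes with the same sign was 60.8% at 1 h, below the 66.6% simulated, and 71.5% at 2 h against 66.3%. The 2 untreated libraries cannot be split, so part of the excess may come from them. Without an untreated library the shared genes numbered 73 or 105 at 1 h and 625 or 609 at 2 h. Without the 0.03 nM 1 h library of experiment 2 there were 106 at 1 h, and without the 0.03 nM 2 h library of experiment 1 there were 2276 at 2 h.

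The share of the 10 nM response reached at 0.03 nM was taken for each gene as the ratio of the log2 fold changes. Over the 919 genes raised at least 2-fold at 10 nM at 1 h its median was 14.7% (quartiles 4.96% and 26.5%; 9.74% in experiment 1 and 17.3% in experiment 2). Over the 1688 such genes at 2 h it was 21.5% (quartiles 8.31% and 36.4%; 23.3% and 19.2%). At 2 h the share was above that of the other raised genes for phagocyte receptors (48.6%; permutation test over genes, two-sided, adjusted p = 0.0028), NF-kB feedback genes (47.6%; adjusted p = 0.0028), and immediate-early genes (42.9%; adjusted p = 0.007). So was that for chemokines (42.1%; adjusted p = 0.007), co-stimulation genes (41.3%; adjusted p = 0.0115) and MAP kinase phosphatases (40.3%; adjusted p = 0.0415). Within each experiment these lists reached 34.9% to 50.5%. For immediate-early genes the 10 nM change itself had shrunk, with list median log2 fold changes of 3.4 at 1 h and 1.89 at 2 h. At 0.03 nM these medians were 1.02 and 0.80, so their share at 2 h does not mark a stronger response at 0.03 nM. The permutation treats genes as independent and leaves out variation between libraries, so its p-values describe the genes alone. Interferon-stimulated genes reached 19.4% (adjusted p = 0.928) and inflammatory cytokines 32.4% (adjusted p = 0.105). At 1 h only the cytokines passed (30.3%; adjusted p = 0.0364). Their share within each experiment was 11.1% and 16.7%, against 9.74% and 17.3% over all raised genes. Without genes of 3 or fewer untreated counts, whose fitted folds are unreliable, they no longer did (28.4%; adjusted p = 0.0525), while the 6 lists of 2 h all still passed. The 1 h share over all raised genes was 8.16% without the 0.03 nM 1 h library of experiment 2.

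**Figure D3:**
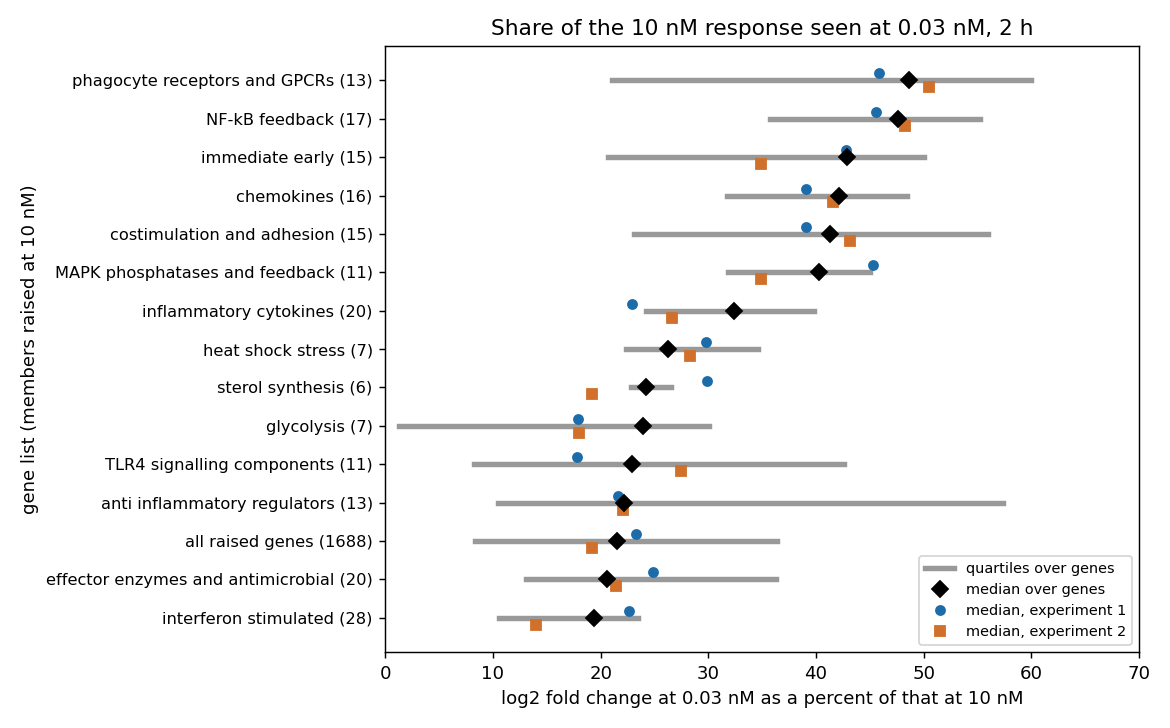
Median share of the 10 nM log2 fold change reached at 0.03 nM at 2 h (percent) for each list, with bars for the quartiles over its genes and points for the median in each experiment. NF-kB feedback genes sit at 47.6% and interferon-stimulated genes at 19.4%, against 21.5% over all 1688 raised genes.

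Between 1 h and 2 h at 0.03 nM, 660 genes changed, 454 upward and 206 downward (edgeR, Benjamini-Hochberg). The largest rises were in Irg1 (8.81-fold), the filament-anchoring gene Lad1 (7.6-fold), Ch25h (7.04-fold), Olr1 (6.32-fold) and Il6 (6.26-fold), and the largest falls in the inhibitory SMAD gene Smad7 (2.65-fold), Egr1 (2.49-fold), the transcription factor gene Tfap4 (2.18-fold), Gpr146 (2.17-fold) and Nr4a1 (2.08-fold). Co-stimulation genes rose in 12 of 15 cases (12 adjusted over the list alone; camera adjusted p = 2.42e-28). NF-kB feedback genes rose in 12 of 18 (14 up and 1 down alone; camera adjusted p = 4.76e-27, or 0.0759 with an estimated correlation). Chemokines rose in 9 of 17 (11 alone; camera adjusted p = 1.66e-19, or 0.072 with an estimated correlation). The count was 285 without the 0.03 nM 1 h library of experiment 1 and 2833 without the 0.03 nM 2 h library of experiment 1. Without the 0.03 nM 1 h library of experiment 1 or 2, Irg1 rose 5.77-fold or 18.6-fold, Olr1 3.82-fold or 18.6-fold and Il6 3.87-fold or 16.4-fold. The call on Irg1 was lost in 8 of the 10 fits without 1 library, and also without a filter on low counts (edgeR adjusted p = 0.0715). Calls on Egr1, Nr4a1 and Olr1 were lost without the 0.03 nM 2 h library of experiment 2. That on Tfap4 was lost without the 0.03 nM 1 h library of experiment 1. With only the groups compared, those on Irg1, Olr1 and Il6 were lost (edgeR adjusted p = 0.202, 0.0814 and 0.108). The share of rises was 68.8%, and 54.1% under library totals.

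Between 1 h and 2 h at 10 nM, 5526 genes changed, 2747 upward and 2779 downward, with shares of rises of 49.7% and, under library totals, 29.2% (edgeR, Benjamini-Hochberg). Interferon-stimulated genes rose in 26 of 31 cases (28 adjusted over the list alone; camera adjusted p = 6.6e-10, or 0.644 with an estimated correlation). The largest rises were in the BTB-domain gene Abtb2 (30.5-fold), Socs1 (23.7-fold), Mx1 (21.9-fold), the ubiquitin ligase adaptor gene Spsb1 (19.9-fold; 30.9-fold without the 10 nM 1 h library of experiment 2) and the cyclin gene Ccnj (17.1-fold). Immediate-early genes fell in 17 of 22 cases (17 alone; camera adjusted p = 2.09e-17, or 0.474 with an estimated correlation), with Nr4a1 28.2-fold, Egr1 12.4-fold and Fos 8.19-fold lower. Lpar6 was 13.5-fold, Cxcr4 11.3-fold and the uncharacterised gene BC031353 10.6-fold lower. Among cytokines and chemokines, Tnf, Il10, Ifnb1, Cxcl1 and Cxcl2 fell by 1.04, 1.04, 1.31, 1.57 and 1.99. Il6, Il12b, Cxcl10, Ccl5 and Nos2 rose by 0.92, 0.65, 1.65, 2.01 and 3.79. The call on Ccl5 was lost without the 10 nM 1 h library of experiment 1 (0.105). Il1b, Ptgs2, Nfkbia, Tnfaip3 and Ccl3 did not pass (-0.75, -0.64, 0.06, -0.20 and 0.06). Il1b and Ptgs2 passed with a block for the experiment (adjusted p = 0.00861 and 0.0318), in limma (adjusted p = 0.02 and 0.0162), under library totals (adjusted p = 0.0393 and 0.0255) and with only the groups compared (adjusted p = 0.000402 and 1.17e-06). Tnfaip3 passed under library totals (adjusted p = 0.0193) and with only the groups compared (adjusted p = 0.000474). Genes changed against untreated cells in the same direction at both times numbered 167 up and 13 down at 0.03 nM (independent lists 11.9 and 0.471; covariance 0.158 against 0.037 simulated; r = 0.634 against 0.494). At 10 nM they numbered 2021 up and 1985 down (685 and 712; 1.4 against 0.0367; 0.828 against 0.469). The share of all genes with the same sign was 65.8% at 0.03 nM and 77.6% at 10 nM, against 66.6% and 66.3% simulated. Here too part of the excess may come from the shared untreated libraries, and at 0.03 nM the shared genes numbered 73 or 106 without either of them and 106 without the 0.03 nM 1 h library of experiment 2.

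The change with time differed between the doses at 2846 genes, 1348 more upward and 1498 more downward at 10 nM than at 0.03 nM (edgeR interaction term, Benjamini-Hochberg). The largest positive terms were in the uncharacterised gene E130102H24Rik (4.21 ± 0.30), Ccnj (4.12 ± 0.26), Mx1 (4.09 ± 0.65), and the interferon-inducible genes Slfn1 (4.0 ± 1.08) and Iigp1 (3.74 ± 0.55). Among the largest negative ones were Nr4a1 (-3.76 ± 0.23), Egr2 (-3.57 ± 0.19), the kinase gene Plk3 (-3.4 ± 0.21) and Dusp8 (-3.17 ± 0.36). By list, 19 of 22 immediate-early genes were more downward (19 adjusted over the list alone, with 1 upward; camera adjusted p = 5.89e-21, or 0.316 with an estimated correlation). Of 31 interferon-stimulated genes 16 were more upward (20 alone; camera adjusted p = 9.35e-11, or 0.69 with an estimated correlation). Among the genes given at each step, Tnf, Cxcl1, Cxcl2, Fos and Egr1 had terms of -1.6, -2.13, -2.55, -2.23 and -2.32. Il12b, Il6, Ifnb1 and Ccl3 had terms of -1.12, -1.72, -2.14 and -1.26, and Nos2 one of 3.74 (adjusted p = 0.0449). Without the 0.03 nM 1 h library of experiment 2 that of Nos2 was 0.335 (adjusted p = 0.938). Its call was also lost with only the groups compared (0.0752), in DESeq2 (0.0542), without a filter (0.116) and after removal of a length trend (0.0638). Without the 0.03 nM 1 h library of experiment 1 or 2 the term of Il6 was -1.03 (not called, adjusted p = 0.126) or -3.12, and the call on Ifnb1 was lost without the 0.03 nM 2 h library of experiment 2 (0.0969). In limma on the authors' values Il12b was not called (-0.26; adjusted p = 0.0977), and the term of Il6 turned to 0.03 (adjusted p = 0.93). With a block for the experiment Il1b and Ccl5 passed as well (-1.12 and 1.70; adjusted p = 0.0144 and 0.0344). The count was 1897 without the 10 nM 1 h library of experiment 1, and the call on Slfn1 was lost in 8 of the 10 fits without 1 library (highest adjusted p = 0.144) and with only the groups compared (0.0648). The terms of Mx1, Slfn1 and Iigp1 were 3.31, 2.65 and 3.08 without the 0.03 nM 1 h library of experiment 2. That of Slfn1 was 4.68 without the one of experiment 1 and 5.04 without the 10 nM 1 h library of experiment 2. The share of upward terms was 47.4%, and 30.9% under library totals.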

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

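The interaction of dose and time and the fits without 1 library were planned tests, while Id1 and Id3 were named only after their values were seen. The change from 1 h to 2 h differed between 10 nM and 0.03 nM in 2846 genes by a test of the difference itself, with 1348 more upward and 1498 more downward at 10 nM (edgeR). Of 119 genes named in the text, 83 were among them (against 2846 of all 12918 tested), 28 more upward and 55 more downward at 10 nM. Many of the named genes were chosen for large changes in these data, the interaction included, so a high count is built in. No explanation of these differences was tested.

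The log2 differences above 0 were E130102H24Rik 4.21, Ccnj 4.12, Mx1 4.09, Slfn1 4.0, Iigp1 3.74, Nos2 3.74, Spsb1 3.68, Socs1 3.47, Cxcl9 2.45, Zfp870 2.36. Next came Zkscan14 2.33, Mmp13 2.31, Zfp955b 2.28, Hk2 2.22, Pfkfb3 2.14, Txnip 2.14, Zfp60 1.86, Rnd1 1.78, Irf8 1.73, Cish 1.46. Then came Gbp3 1.46, Gbp2 1.23, Wdr5b 1.19, Ifih1 1.18, Msr1 0.79, Ywhaz 0.44, Dnaja1 0.43, Actb 0.39.

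The log2 differences below 0 were Insig1 -0.40, Abcg1 -0.50, Gadd45b -0.55, Zc3h12a -0.57, Cd14 -0.66, Vcam1 -0.71, Tnip1 -0.73, Cebpa -0.77, Nr1h3 -0.78, Icam1 -0.87. Next came Irak2 -0.94, Zfp36 -0.94, Slc5a3 -0.94, Nfkbie -1.01, Tnfsf9 -1.06, Ier3 -1.07, Il12b -1.12, Slc6a12 -1.13, Errfi1 -1.16, Cebpb -1.17. Then came Ccne2 -1.19, Tlr2 -1.25, Ccl3 -1.26, Arl4c -1.26, Hspa1b -1.29, Gpr84 -1.38, Bmf -1.41, Id1 -1.56, Tnf -1.6. After these came Il6 -1.72, AI467606 -1.80, Slco4a1 -1.81, Abhd15 -1.91, Maff -1.93, Lpar5 -1.97, Cxcl1 -2.13, Ifnb1 -2.14, Dnajc28 -2.18, Cd83 -2.21. Lower still stood Fos -2.23, Olr1 -2.30, Egr1 -2.32, BC031353 -2.49, Ch25h -2.52, Icosl -2.55, Cxcl2 -2.55, Cxcr4 -2.70, Cnr2 -2.83, Id3 -2.83. The next were Lpar6 -2.96, Csf2 -3.02, Dusp8 -3.17, Plk3 -3.4, Egr2 -3.57, Nr4a1 -3.76.

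Of the 83 calls, 64 held in each of the 10 fits without 1 library and 19 were lost in at least 1. These are given with the number of fits that lost them and the highest adjusted p, by the library whose absence gave it. Without 10 nM 1 h of experiment 1 this was Wdr5b (8 fits; 0.178), Actb (2 fits; 0.0909), Insig1 (7 fits; 0.166) and Gadd45b (2 fits; 0.0635). Without 10 nM 1 h of experiment 2 this was Dnaja1 (1 fit; 0.058). Without 10 nM 2 h of experiment 1 this was Id1 (5 fits; 0.0862). Without 0.03 nM 1 h of experiment 1 this was Vcam1 (7 fits; 0.132) and Il6 (1 fit; 0.126). Without 0.03 nM 1 h of experiment 2 this was Nos2 (8 fits; 0.938), whose difference of 3.74 fell to 0.335 there. The differences of Mx1, Slfn1 and Iigp1 were 3.31, 2.65 and 3.08 without this library. That of Il6 was -3.12 there and -1.03 without 0.03 nM 1 h of experiment 1. Without 0.03 nM 2 h of experiment 1 this was Slfn1 (8 fits; 0.144), Gbp2 (2 fits; 0.0546), Slc5a3 (6 fits; 0.209) and Csf2 (5 fits; 0.127). Without 0.03 nM 2 h of experiment 2 this was Ifih1 (6 fits; 0.163), Nr1h3 (5 fits; 0.0875), Nfkbie (2 fits; 0.0924), Cebpb (2 fits; 0.0731), Gpr84 (1 fit; 0.0546) and Ifnb1 (1 fit; 0.0969).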

How the results depend on the processing

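Of the tests here, removal of the length trend was chosen only after the result was seen, and the other alternatives were fixed beforehand. With 2 libraries per group, each fit that leaves out a library assumes that the lone one varies like the other groups, and depth limits genes with few counts over the untreated libraries. For named genes, 8406 results over all alternatives kept their side of the threshold, with direction checked only where the main fit made a call. In 213 a call was lost, in 89 a call was gained, and 2 calls of the main fit reversed direction. The 2 reversed were Actb at 10 nM against 0.03 nM at 1 h under library totals (-0.05409) and the interaction of Il6 under limma on the authors' values (0.02911). Changes of direction in genes without a call in the main fit are not counted there. The interaction of Cxcl10, -0.04 in the main fit, was 0.43 without the 0.03 nM 1 h library of experiment 1. It was -0.74 without that of experiment 2. Library totals in place of TMM, which counts the general shift of all genes, moved the genes changed at 10 nM 1 h to 8035 and those of 10 nM against 0.03 nM at 1 h to 7789. They moved the share at 2 h to 27.41% and the calls shared between times at 10 nM to 7147. The share at 2 h was 18.27% with limma on the authors' values and 26.25% over genes raised at least 4-fold. The cause was not tested for these, for Il6, for the estimated correlation or for the libraries left out. For interferon-stimulated genes the estimated correlation includes the difference between experiments, so their loss there does not decide whether the list shifted. Only the groups compared, which leaves fewer samples, gave 655 genes at 0.03 nM 2 h, 198 for 2 h against 1 h at 0.03 nM and 613 calls shared between doses at 2 h. With an estimated correlation the lists shifted numbered 7, 3, 7, 2, 7 and 3 for 0.03 nM 1 h, 0.03 nM 2 h, 10 nM 1 h, 10 nM 2 h and the doses compared at 1 h and 2 h, against 11, 11, 14, 13, 14 and 13.

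Without each library in turn, genes changed ran from 78 (untreated, experiment 1) to 251 (0.03 nM 2 h, experiment 1) at 0.03 nM 1 h, and from 650 (untreated, experiment 2) to 3128 (0.03 nM 2 h, experiment 1) at 0.03 nM 2 h. For 2 h against 1 h at 0.03 nM they ran from 285 (0.03 nM 1 h, experiment 1) to 2833 (0.03 nM 2 h, experiment 1), and for the interaction from 1897 (10 nM 1 h, experiment 1) to 3644 (0.03 nM 2 h, experiment 2). The share at 1 h ran from 8.164% (0.03 nM 1 h, experiment 2) to 18.75% (that of experiment 1). Calls shared between doses ran from 73 (untreated, experiment 1) to 218 (0.03 nM 1 h, experiment 1) at 1 h and from 609 (untreated, experiment 2) to 2276 (0.03 nM 2 h, experiment 1) at 2 h. Those shared between times at 0.03 nM ran from 73 (untreated, experiment 1) to 219 (0.03 nM 2 h, experiment 1). The counts at 10 nM stayed within 1.5 times, at 3387 to 5815 at 1 h and 6481 to 8241 at 2 h. DESeq2 gave 253, 1350, 4520 and 7275 genes for the 4 groups against untreated cells, and DESeq2 size factors 191, 1246, 4753 and 7576. No filter gave 222, 1322, 4659 and 7467, and removal of the length trend 225, 1724, 5611 and 8113. The replicate block gave 220, 1394, 4947 and 7695 and moved no count by more than 1.5 times.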

Other observations

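The tests of Smad6 with Id1 and Id3 (a single library and scaling), of the earlier induction, and of stromal cells, and the reading of GC content, were chosen only after the result was seen, as were the genes and gene family described here. At 2 h, 4 genes of the BMP pathway stood higher at 0.03 nM than at 10 nM. Smad6 and Smad7 encode inhibitory SMADs, and Id1 and Id3 encode helix-loop-helix inhibitors that BMP signalling induces. At 0.03 nM, Smad6, Smad7, Id1 and Id3 rose at 1 h by 3.47 ± 0.22, 2.21 ± 0.14, 3.36 ± 0.33 and 3.27 ± 0.12 and at 2 h by 3.89 ± 0.22, 0.80 ± 0.14, 3.05 ± 0.33 and 3.01 ± 0.12 (edgeR). At 10 nM against 0.03 nM at 2 h their log2 differences were -3.09 ± 0.21, -0.44 ± 0.15, -2.17 ± 0.32 and -2.14 ± 0.11 (edgeR adjusted p = 2.3e-07, 0.0246, 0.000126 and 2.53e-08).

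All 4 genes kept the call under the other scalings, but library totals moved the median of all genes by -0.488 here and DESeq2 size factors by 0.03, so neither could have ended the calls. For Smad7 a scaling difference thus cannot be told apart from a change. For Smad6, Id1 and Id3 the smallest difference, -2.14 ± 0.11, is larger in size than the largest of these moves. A scaling difference of the size seen between these scalings thus does not account for it. A larger shift of all RNA was not measured, so it is not excluded. The call on Smad7 may rest on single libraries, since 3 of the 4 genes kept it without the 10 nM 2 h library of experiment 1 or the 0.03 nM 2 h library of experiment 2. For Smad6, Id1 and Id3 0 fits lost the call, but these 3 were grouped once their calls were seen to hold, so this is no test. Their 2 h values in experiments 1 and 2 do bear on it. At 0.03 nM against 10 nM, Smad6 stood at 16.0 and 13.9 against 2.0 and 1.5 CPM. Id1 stood at 5.1 and 6.8 against 1.3 and 1.4 CPM, and Id3 at 158 and 180 against 39.5 and 37.2 CPM. The difference was thus present in both experiments, which argues against a single library as its source for these 3 genes. An induction at 10 nM that equals that at 0.03 nM at 1 h and has passed by 2 h does not hold for Smad6 and Smad7, as 2 of the 2 were lower at 10 nM at 1 h (-2.25 ± 0.20 and -1.01 ± 0.13). A peak before 1 h stays open, since no earlier time was sampled. An induction at 10 nM that has passed by 2 h may apply to Id1 and Id3. At 1 h 0 of them were lower at 10 nM (-0.62 ± 0.27 and 0.69 ± 0.11, edgeR adjusted p = 0.106 and 0.000335). Id3 was higher there, so its induction was not equal between the doses. Both fell from 1 h to 2 h at 10 nM.

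Genes with Zfp symbols, which encode zinc finger proteins, fell as a family at 10 nM. Of 322 tested, 214 fell and 26 rose at 1 h (median -1.10; 66.5% down against 17.1% of other genes) and 220 fell and 33 rose at 2 h (median -1.0; 68.3% against 29.1%), while at 0.03 nM the median was -0.01 at 1 h and -0.16 at 2 h. Zfp36, an mRNA decay factor also counted here, rose. Length, GC content and expression level do not account for the fall: 0 of 10000 matched sets of other genes had a median as low, the lowest at -0.197. The Zfp median lay -1.09 from that of all genes under each scaling. A factor per library cannot change this difference, so that test excludes scaling by construction only. Reads shared within the family cannot be told apart from separate changes: the SD of the changes was 1.4 against a median of 1.1 in matched sets, of which 398 were as high. No biological explanation was tested.

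In the 0.03 nM 2 h library of experiment 2, long gene models had fewer counts than in experiment 1. The median log2 difference was 0.18 among the 2787 shortest genes and -0.22 among the 2786 longest. Relative counts correlated with length at rho = -0.607 in that library against 0.0015 to 0.369 in the other untreated and 0.03 nM libraries. GC content alone does not account for it, as the correlation with length at fixed GC was -0.689. The bound set beforehand was not reached (0.482 for GC at fixed length), so this exclusion rests on a value chosen afterwards. Stromal cells in experiment 2 do not account for it either, since 4 other groups, in which stromal genes were also higher in experiment 2, had correlations above the bound of -0.3. After removal of a length trend, 2172 genes changed at 0.03 nM 2 h without replicate 1 against 1391 without replicate 2 (3128 and 1208 before, seen when the test was chosen in place of one whose outcome was fixed by construction). Length-dependent recovery of RNA may explain part of this imbalance, and its share cannot be told apart from other causes on these values. No biological explanation was tested.

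Other differences between the experiments are given as values. Col1a1, a collagen gene of the stromal list chosen after its values were seen, stood at 7.69 CPM in the untreated library of experiment 1 and 17.2 CPM in that of experiment 2. Irf7, an interferon regulator also chosen then, stood at 119 CPM at 0.03 nM 1 h in experiment 1 and 331 CPM in experiment 2.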
